A study of Mus musculus with 80 samples.

How the data were processed

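Kidneys of 40 C57BL/6 mice, an inbred laboratory strain fed freely on regular chow, were measured on 80 nylon filter arrays of spotted cDNA clones. Per the labels, total RNA was extracted on silica columns after bead disruption of the tissue and copied into cDNA with a radioactive phosphorus label. Each mouse was hybridised to 2 filters, set A and set B, which hold different clones, so each mouse was 1 replicate in each set. The series text says only that mice were compared by age and sex, and no test is named there.

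The deposited values were scores: in each of the 80 columns they had mean 0 and SD 1, so a score is a distance from the array's mean in units of that array's SD. Image reading, background correction and the scale before this transformation (log or linear) are not given in the sources used here. All differences are therefore in array SDs, and none can be read as a fold. No columns of values were left out (0), none of the values was missing, and no 2 arrays held identical values. Each set held 8448 clones, 16896 in all.

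The labels gave sex and age in days. The mice fell into 4 age groups of each sex with 5 mice in each: 17 to 44, 169 to 194, 476 to 499 and 704 to 743 days. The youngest group mixed 5 mice of 17 to 21 days with 5 older ones. For 1 male of 714 days, the description named another mouse than the title, and the sex and age fields were followed. Serial numbers in the titles ran in 5 blocks, each with 1 male and 1 female of every age group. These blocks, called rounds of arrays below, were inferred from the numbers, since no label says what they stand for.

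Groups, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. That plan kept a table as deposited only if the medians and interquartile ranges of its arrays lay within 5% of each other. Interquartile ranges departed by up to 7.63% in set A and 4.22% in set B, and medians by up to 5% and 7% of an array SD. Both sets were therefore quantile normalized, each on its own. Each set was fitted separately with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and Benjamini-Hochberg adjustment ran over the clones of both sets together. A clone was called at an adjusted p under 0.05. The age slope was fitted per year of 365 days with sex as a second term. The other 4 comparisons came from a model of the 8 sex and age means: 169 to 194 minus 17 to 44 days, 704 to 743 minus 169 to 194 days, male minus female, and an F test for a sex difference that varied with age. Every fit used all 40 mice, and the number of arrays limits the precision of each value. The median standard error was 0.0372 array SD per year for the slope, 0.0779 for both age contrasts and 0.0551 for sex.

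Clones were named from the platform table supplied with the values. It gave 1 symbol to 9663 clones (7151 genes), several to 436, and did not list 6797, which stay unnamed here. Symbols were checked by gene identifier against a RefSeq table of the GRCm38.p6 assembly: 9641 matched, 22 did not, and 0 symbols changed. That table served for names only. No build is given for the clones, so no coordinates are reported.

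The naming rule took, per comparison, up to 10 called clones with 1 symbol in each direction by size of effect. Where none was called, it took the 3 with the smallest p in each direction as values that did not pass. It added up to 4 members of each list that passed, the sex chromosome genes and Kl, for which no clone had a symbol. A gene with several clones was represented in list tests by the clone of highest brightness rank, and its other clones are given beside it.

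The 32 gene lists covered nephron segments (proximal tubule, loop of Henle and distal tubule, collecting duct, podocyte), other cell types (endothelial, fibroblast and extracellular matrix, B and plasma cell, T and NK cell, macrophage and myeloid, erythroid and blood) and neighbouring tissues (adrenal, adipocyte, skeletal muscle, liver). They also covered MHC and interferon, complement and coagulation, tubular injury, oxidative phosphorylation, the tricarboxylic acid cycle, cytosolic ribosome, cell cycle, imprinted and juvenile growth, senescence, antioxidant and glutathione, chaperones, proteasome, fatty acid oxidation, cholesterol synthesis, male-biased and female-biased kidney genes, and Y-linked and X-linked genes. Lists with at least 3 genes on the arrays (27) were tested with limma's cameraPR at a preset correlation of 0.01, adjusted over lists within a comparison, and again with the correlation estimated from residuals. The other 5 are given gene by gene. A list's score in a mouse is the mean deviation of its clones from their means over all mice. Scores were compared by permutation tests, all two-sided, with 100000 resamples or, where stated, exactly.

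The fits were tested on simulated data: residuals of the 16896 real clones with the mice shuffled, and 200 clones changed by known amounts in each of 5 runs. For male minus female, 42.4% of changes of 0.2 array SD and 94.8% of changes of 0.4 were called. For 704 to 743 minus 169 to 194 days the shares were 14% and 77.2%, for 169 to 194 minus 17 to 44 days 14.4% and 77.6%, and for slopes of 0.2 and 0.4 per year 87.2% and 98.8%. The interaction recovered 6.8% at 0.4 and 74% at 0.8. False calls made up between 0.949% (interaction) and 6.72% (age slope) of calls. A list of 59 genes shifted by -0.05 was called in 4 of 5 runs for 704 to 743 minus 169 to 194 days and for sex, 2 of 5 for 169 to 194 minus 17 to 44 days and 5 of 5 for the age slope. Lists that were not shifted were called in 1, 5, 0 and 2 of 125 tests, in the same order.

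Alternatives were the values as deposited, median and interquartile scaling, no dim clones (the dimmest 25%), trended and robust variances, array weights, the round as a block, adjustment within each set, a threshold of 0.1, gene means, and fits without single mice, without the mice of 17 to 21 days or without the mouse with conflicting labels. Other forms of age, ordinary least squares, fits of the compared mice only, a rank form of the list test and an estimated correlation were also planned. Leaving out 8 mice with outlying arrays, that with the block, the scaling for lists, the tricarboxylic acid list without shared genes, and exact sign flips of score differences within sex and round were added after seeing the data. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.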

Results

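Transcripts were measured in whole kidneys of male and female C57BL/6 mice from shortly before weaning to about the end of the second year of life. The series compares ages and sexes. Each of the 8 groups held 5 mice, and each mouse was measured on 2 filters that together carried 16896 clones. Values are normalized z scores, so differences are in array SDs, and the scale before the z transformation is unknown. The mean correlation of an array with the others of its set ran from 0.891 to 0.965 in set A and from 0.916 to 0.976 in set B. The first principal component held 19.7% of the variance in set A and 24.2% in set B. The 5 rounds of arrays accounted for 64.8% and 66.9% of the variance along it (permutation p = 1e-04 in both sets, the smallest that the resamples can give). Scores along it did not pass permutation tests for age group (p = 0.618 and 0.910) or sex (p = 0.560 and 0.363). Every round held 1 male and 1 female of each age group, so rounds and groups could be told apart, and differences within rounds are given beside the main results.

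**Figure D1:**
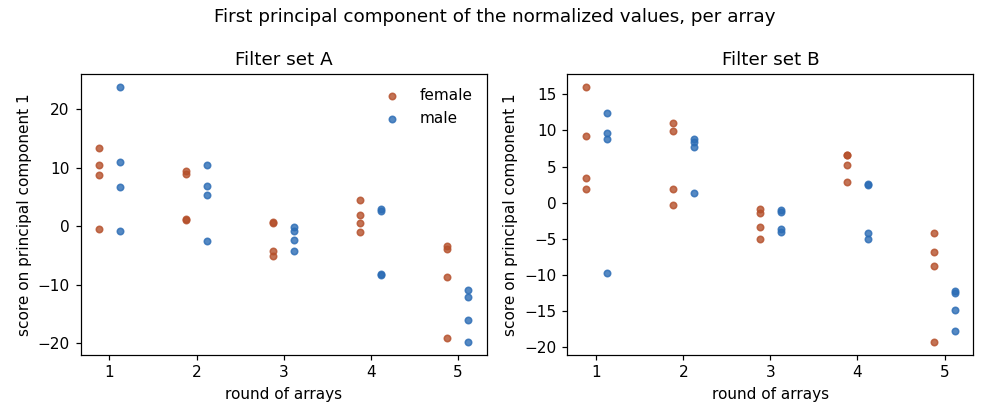
Score of each array on the first principal component of its filter set (vertical axis) by round of arrays (horizontal axis), with males in blue and females in red. Rounds account for 64.8% of the variance along the component in set A and 66.9% in set B.

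By the called clones, male kidneys had more Selenop, Cyb5a, Odc1 and Fpgs transcript than female kidneys, and less Cdk8, Hsd3b1 and Oat. For Hsd3b1 and Oat, a brighter clone differed in the same direction without passing, and Hsd3b1 is also on the list of adrenal genes. Selenop (spot 16010), which encodes the plasma selenium carrier selenoprotein P, averaged -0.260 ± 0.172 in males and -0.704 ± 0.119 in females (SD, n = 20 each). The difference of 0.443 ± 0.0444 array SDs (SE, limma adjusted p = 2.33e-08) had the same sign in 20 of the 20 couples of a male and a female of one age group and round. Couples of the youngest group were not matched in days of age. Round 1 paired a male of 43 days with a female of 17, and round 4 a male of 17 days with a female of 40. Sex and age are therefore mixed in such couples. Cyb5a (spot 316), the electron donor cytochrome b5, differed by 0.366 ± 0.0439 (adjusted p = 1.76e-06, 19 of 20 couples). Odc1, ornithine decarboxylase, the androgen-responsive first enzyme of polyamine synthesis, differed by 0.346 ± 0.0561 (adjusted p = 8.19e-04, 18 of 20), and its other clone by 0.392 (adjusted p = 0.00194).

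Comparison of the sexes over all ages called 18 of 16896 clones with limma, 12 higher and 6 lower in males, 14 of them in set A and 4 in set B. Of these, 15 clones stood for 14 named genes. With the round as a block 19 were called, including all 18. At an unadjusted p under 0.05 there were 757 clones, against a nominal 844.8. The median was 675 when sexes were shuffled within age groups, without keeping the rounds balanced. The real count was 1045 with the block and 1306 with array weights. Fpgs, which adds glutamates to folate, differed by 0.342 ± 0.0538 (adjusted p = 5.40e-04, 19 of 20 couples), and Pecr, a peroxisomal enoyl-CoA reductase, by 0.290 ± 0.0502 (adjusted p = 0.00226, 18 of 20). The epoxide hydrolase Ephx2 differed by 0.306 ± 0.0576 (adjusted p = 0.00646, 18 of 20), malic enzyme Me1 by 0.310 ± 0.0662 (adjusted p = 0.0321, 18 of 20), Grhpr by 0.282 ± 0.0568 (adjusted p = 0.0151, 17 of 20) and the ketone body enzyme Acat1 by 0.280 ± 0.0582 (adjusted p = 0.0242, 17 of 20). The brighter clone of Ephx2 (0.129) and the other clones of Me1 (0.0431 and 0.183, both brighter, and 0.186) had smaller differences of the same sign that did not pass.

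Among the genes lower in males, Cdk8, a kinase of the Mediator complex, had the largest difference of a named gene, -0.643 ± 0.0836 (adjusted p = 1.01e-05, 18 of 20 couples). Hsd3b1, a steroid dehydrogenase, differed by -0.280 ± 0.0535 (adjusted p = 0.00788, 19 of 20). Its other, slightly brighter clone differed by -0.176 and did not pass (limma adjusted p = 0.760). Hsd3b1 also belongs to the list of the neighbouring adrenal, which did not pass between the sexes. Kpna3, a nuclear import receptor, differed by -0.301 ± 0.0582 (adjusted p = 0.00884, 17 of 20), but this was the dimmest of its 4 clones, and the others differed by -0.0444, -0.0767 and 0.0418 without passing. Oat, the ornithine aminotransferase, differed by -0.223 ± 0.0411 (adjusted p = 0.00502, 18 of 20), while its brighter clone was at -0.123 and did not pass (adjusted p = 0.982). Gsta4, a glutathione transferase, differed by -0.204 ± 0.0436 (adjusted p = 0.0321, 17 of 20). The clone with the smallest p has no symbol here (spot 3145 of set A): males averaged -0.641 ± 0.207 and females 0.0805 ± 0.154 (SD, n = 20 each), and the ranges of the sexes did not overlap. Unnamed spots 982 and 2601 were higher in males by 0.380 ± 0.0666 and 0.261 ± 0.0479.

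**Figure D2:**
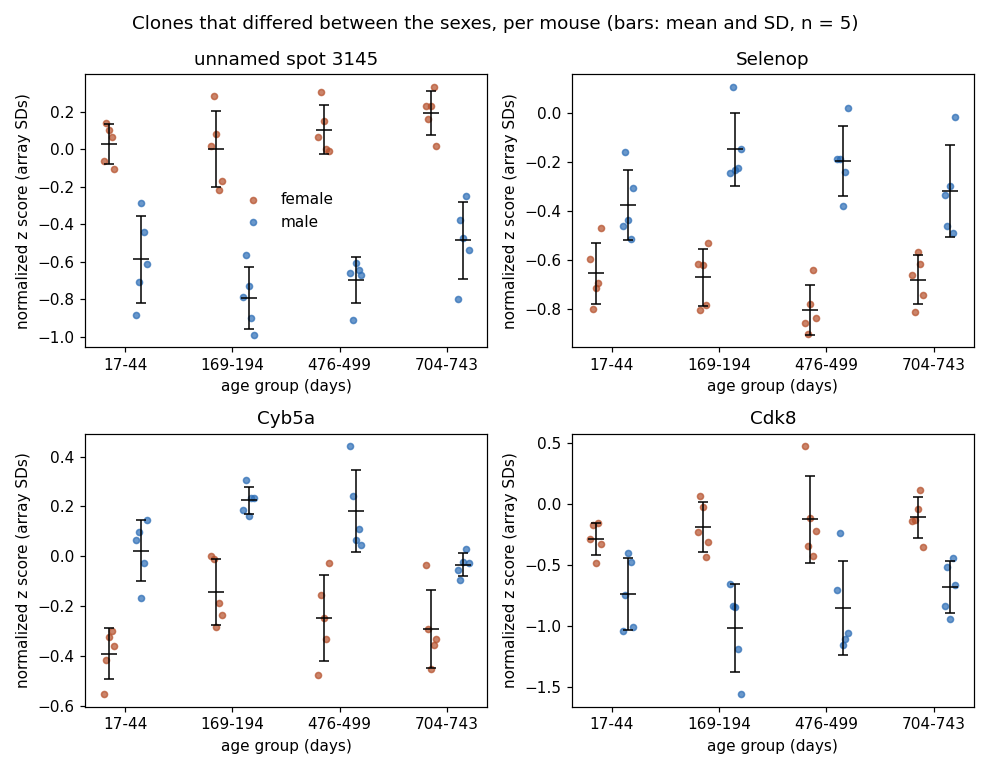
Normalized z score (array SDs) of each mouse by age group for unnamed spot 3145, Selenop, Cyb5a and Cdk8, with males in blue, females in red, and bars for mean and SD (n = 5). For spot 3145 the males lie between -0.990 and -0.248 and the females between -0.217 and 0.334.

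The calls for Me1, Ephx2, Pecr, Grhpr, Acat1, Hsd3b1 and Gsta4 did not hold without the 5 mice of 17 to 21 days, where 11 clones were called. The called clones of Ephx2, Grhpr and Kpna3 were among the dimmest 25% of their set. Without the dimmest 25%, 16 clones were called, 15 of them among the 18. Without the 8 mice with outlying arrays, Pecr (adjusted p = 0.105, alternatives from 0.00123 to 0.105) and Gsta4 (adjusted p = 0.605, alternatives from 0.0203 to 0.605) did not pass. With single mice left out, Me1 was called in 24 of 40 fits and Gsta4 in 22, with adjusted p up to 0.0729 (without male 169 to 194 days replicate 2) and 0.0747 (without female 17 to 44 days replicate 4), and Acat1 was not called without male 169 to 194 days replicate 2 (0.0533).

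The list of androgen-responsive or male-biased kidney genes was higher in males (camera adjusted p = 1.34e-04, and 5.56e-04 with an estimated correlation). Of its 7 measured genes 5 were higher, with a median difference of 0.0452. Odc1 was called over all clones, and 3 genes passed when adjusted over the list alone. Besides Odc1 these were Ces1f, a carboxylesterase (0.217 ± 0.0562, 17 of 20 couples), and Cndp2, a dipeptidase (0.149 ± 0.0491, 16 of 20). Acy3, an aminoacylase, was at -0.0964 ± 0.0679. A rank form of the list test gave an adjusted p of 0.692 (alternatives from 2.32e-08 to 0.692), and without Odc1 the 6 remaining genes gave an adjusted p of 0.290. The female-biased list did not pass (6 genes, adjusted p = 0.848), although its member Gsta4 was called, the 1 gene that also passed when adjusted over the list alone. Antioxidant and glutathione genes did not pass as a list (17 of 27 higher, adjusted p = 0.513), with 4 genes past the threshold adjusted over the list alone and 1 over all clones, and neither did collecting duct markers (6 of 7 lower, adjusted p = 0.295).

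Clones of sex chromosome genes did not separate males from females, so they did not check the sex labels. The clones of Xist, Eif2s3y and Eif2s3x were among the dimmest 25% of their set. Unnamed spot 3145 did divide the labelled sexes without overlap, although it was picked by these same labels. The clones of the Y-linked genes Eif2s3y and Uty differed between males and females by 0.0374 ± 0.0635 and 0.0118 ± 0.0603, and Xist, which is transcribed from the inactive X, by -0.0344 ± 0.0515. Among X-linked genes that escape inactivation, Ddx3x (0.0206, other clones 0.02496 and 0.0806), Eif2s3x (0.0827) and Kdm5c (0.0566) did not pass, nor did Kdm6a (-0.151 ± 0.0629, adjusted p = 0.982, other clones -0.0446 and 0.0157). The X-linked list as a whole did not pass (5 genes, adjusted p = 0.848).

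Genes of oxidative phosphorylation were lower at 704 to 743 days than at 169 to 194 days. Of the 59 measured, 48 were lower and 11 higher, with a median difference of -0.04998 array SD (camera adjusted p = 1.17e-05, 0.00591 with an estimated correlation and 2.04e-05 with the round as a block). The list score averaged 0.0256 ± 0.0406 at 169 to 194 days and -0.0278 ± 0.0326 at 704 to 743 days (SD, n = 10 each), a difference of -0.0535 (permutation p = 0.00312). Cytochrome c oxidase subunits Cox7b (-0.225 ± 0.0930, 7 of 10 couples), Cox5a (-0.156 ± 0.0661, 7 of 10) and Cox8a (-0.145 ± 0.0776, 5 of 10) and the ATP synthase subunit Atp5a1 (-0.146 ± 0.0676, 7 of 10) had the smallest p among the members. The Cox7b and Cox5a clones were among the dimmest 25% of their set, and the list also passed without such clones. Cox8a was at -0.0650 without male 169 to 194 days replicate 4. No member passed alone: limma called 0 over all clones and 0 adjusted over the list alone, and 3 had an unadjusted p under 0.05.

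Split by complex after the list had passed, 10 of 11 cytochrome c oxidase genes were lower (median -0.0674), as were 19 of 22 complex I genes (median -0.0415), 11 of 15 ATP synthase genes (median -0.0490), 3 of 4 complex II genes (median -0.0748) and 4 of 6 complex III genes (median -0.00939). The score difference was below 0 in each of the 5 rounds (-0.0376, -0.103, -0.0262, -0.0847 and -0.0158), and was -0.0626 in males and -0.0443 in females, a difference between the sexes that did not pass (exact permutation p = 0.673). The score averaged -0.00681 ± 0.0294 at 17 to 44 days and 0.00900 ± 0.0321 at 476 to 499 days (SD, n = 10 each).

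**Figure D3:**
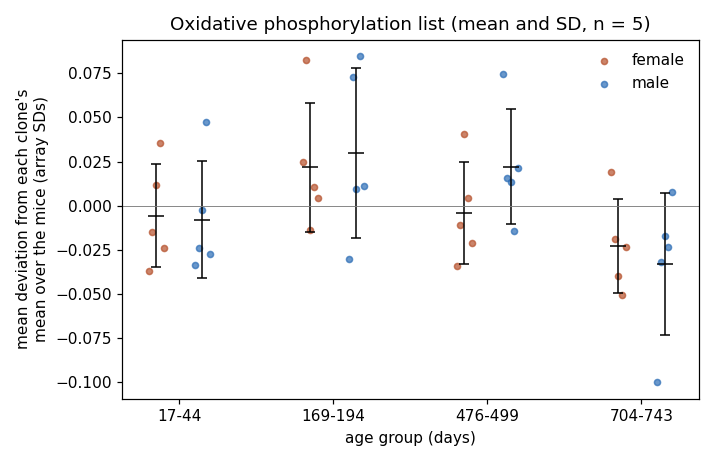
Mean deviation of the oxidative phosphorylation clones from their means over all mice (array SDs), one point per mouse, by age group, with males in blue, females in red, and bars for mean and SD (n = 5). At 704 to 743 days the females average -0.0227 and the males -0.0330, against 0.0217 and 0.0296 at 169 to 194 days.

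Tricarboxylic acid cycle genes were also lower at 704 to 743 days (15 of 21, median -0.0566, camera adjusted p = 0.0108), but the call was lost with adjusted p = 0.113 with an estimated correlation (alternatives from 0.00328 to 0.113). With the round as a block the adjusted p was 0.0122, and the score difference of -0.0542 (permutation p = 0.0302) was below 0 in 5 of 5 rounds. Examples were Idh3b, a subunit of isocitrate dehydrogenase (-0.155 ± 0.0716, 10 of 10 couples), Dlat of the pyruvate dehydrogenase complex (-0.136 ± 0.0684, other clones -0.0748 and -0.135) and Suclg1 (-0.109 ± 0.0602), while Pdha1 was at 0.118 ± 0.0645 and its other clone at -0.0555. The Idh3b clone was among the dimmest 25% of its set. Limma called 0 members over all clones and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. The succinate dehydrogenase genes, 4 in number, belong to both lists, and the other 17 gave an adjusted p of 0.0290. Without male 169 to 194 days replicate 1 (adjusted p = 0.0675), male 169 to 194 days replicate 2 (0.0850) or female 704 to 743 days replicate 4 (0.0818) the list did not pass.

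The male-biased kidney list, higher in males, was lower at 704 to 743 than at 169 to 194 days (5 of 7 genes, median -0.0485, camera adjusted p = 0.0107, 0.0237 with an estimated correlation and 0.0162 with the round as a block). Odc1 (-0.354 ± 0.0793, 9 of 10 couples, other clone -0.256) and Cndp2 (-0.181 ± 0.0694, 8 of 10) passed when adjusted over the list alone, against 0 over all clones. Acy3 was at -0.143 ± 0.0960 and Timd2 at 0.0671 ± 0.0823 (other clones 0.0333 and 0.0241). Acy3 was at -0.0867 without female 169 to 194 days replicate 1, and Timd2 at 0.0247 without female 169 to 194 days replicate 2. Its score difference of -0.0894 did not pass when sex and rounds were both ignored (permutation p = 0.0969), although it was below 0 in 5 of 5 rounds. Exact sign flips within sex and round, added after seeing the data, gave p = 0.0215 (8 of 10 differences below 0). Without Odc1 the list's adjusted p was 0.676, and the rank form gave 0.658 (alternatives from 0.00197 to 0.658). Without male 169 to 194 days replicate 1 (median -0.0162, adjusted p = 0.0675), male 169 to 194 days replicate 2 (median -0.0255, 0.0850) or female 169 to 194 days replicate 1 (median -0.00927, 0.1001) the list did not pass and its median was much closer to 0.

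Single clones did not pass between 169 to 194 and 704 to 743 days: limma called 0 of 16896, and 398 had an unadjusted p under 0.05 against a nominal 844.8. When ages were shuffled between these groups within each sex, the median count was 669. These splits did not keep the rounds balanced, as the real groups did, so they can carry differences between rounds. Of 100 such splits, the real one included, 85 had at least as many as 398. The real count was 676 with the round as a block, 938 with array weights, 988 without the mice with outlying arrays and 1165 without them and with the block. It thus lay on both sides of the nominal value. The smallest p values belonged to Ighm, the immunoglobulin mu heavy chain (0.341 ± 0.0689, adjusted p = 0.241, 10 of 10 couples), Pwwp3b (0.343 ± 0.0953, 10 of 10) and a very dim clone of Gm11545 (1.23 ± 0.333, others 0.111 and 0.0939). In the other direction they belonged to Odc1, the carbonic anhydrase Car2 (-0.284 ± 0.0729, 9 of 10, brighter clone -0.0174) and the cleavage factor subunit Nudt21 (-0.205 ± 0.0582, 9 of 10, brighter clone -0.0462). The second measured gene of the B and plasma cell list, Blnk, was at 0.0730 ± 0.0772.

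The male-biased kidney list was higher at 169 to 194 than at 17 to 44 days (5 of 7 genes, median 0.0918, camera adjusted p = 0.0469, 0.0472 with an estimated correlation). Acy3 (0.379 ± 0.0960, 8 of 10 couples) and Cndp2 (0.238 ± 0.0694, 9 of 10) passed when adjusted over the list alone, against 0 over all clones. Odc1 (0.187 ± 0.0793, other clone 0.133) and Ces1f (0.0918 ± 0.0794) did not. Ces1f was at 0.0526 without female 169 to 194 days replicate 1. With the round as a block the adjusted p was 0.0555, and over the alternatives it ran from 0.00245 to 0.351. Without Odc1 it was 0.148. The list passed in 24 of the 40 fits that left out 1 mouse. The adjusted p reached 0.159 without female 169 to 194 days replicate 1 (median 0.0526) and 0.157 without male 169 to 194 days replicate 2 (median 0.0688). Without male 169 to 194 days replicate 1 the median was 0.0595.

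Single clones did not pass between 17 to 44 and 169 to 194 days either: limma called 0, the lowest adjusted p was 0.933, and 859 clones had an unadjusted p under 0.05 (1206 with the round as a block). Besides Acy3, the smallest p values were those of Sdhd, a membrane anchor of succinate dehydrogenase (0.258 ± 0.0666, 10 of 10 couples), and lactate dehydrogenase Ldha (0.227 ± 0.0592, 8 of 10). In the other direction they were those of Eloa (-0.461 ± 0.127, 9 of 10, other clone -0.0342, and -0.301 without female 17 to 44 days replicate 2), Mepce (-0.297 ± 0.0825, 8 of 10) and Ighm (-0.240 ± 0.0689, 7 of 10). The 169 to 194 day mice enter both age contrasts, so a high or low value there moves them in opposite directions. Over the 20 ways to divide the rounds of that group between the contrasts, the oxidative phosphorylation and male-biased scores stayed above 0 in the first and below 0 in the second in 20 of 20, and the tricarboxylic acid score in 16 of 20. The oxidative phosphorylation genes did not pass in the first contrast (40 of 59 higher, adjusted p = 0.225, and 0.592 with an estimated correlation; score permutation p = 0.0566), nor did the tricarboxylic acid genes (adjusted p = 0.684; score permutation p = 0.302).

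Along the whole age range no clone passed: limma called 0, with 879 at an unadjusted p under 0.05, whereas ordinary least squares called 1 with 916. That clone was Igf2, a fetal growth factor, with a slope of 0.151 ± 0.0287 per year (limma adjusted p = 0.0690, n = 40). With the round as a block 1262 clones had an unadjusted p under 0.05 and 2 were called, Igf2 and Car2. Igf2 had an adjusted p of 0.0218 there (alternatives from 0.0218 to 0.989). Car2 (-0.164 ± 0.0376 per year) had an adjusted p of 0.0391 (alternatives from 0.00488 with array weights to 0.989). Brighter clones of both genes had slopes near 0, at 0.0247 for Igf2 and -0.00222 for Car2. The next smallest p values were those of Slc35f6 (0.110 ± 0.0296, other clone 0.1002), Fbrsl1 (0.107 ± 0.0287), the kidney cadherin Cdh16 (-0.119 ± 0.0308) and the mitochondrial phosphate carrier Slc25a3 (-0.0744 ± 0.0239). None of the 27 lists passed, and the lowest adjusted p was that of oxidative phosphorylation (0.0621, 40 of 59 genes lower, alternatives from 0.0121 to 0.470).

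No clone passed the test for a sex difference that varies with age (limma F test, 0 called, 545 at an unadjusted p under 0.05, and 0 called with 1120 with the round as a block). Bckdk, the kinase of branched-chain ketoacid dehydrogenase, had the smallest p (F = 7.65, unadjusted p of its other clone 0.104): male minus female was -0.169, -0.171, -0.313 and 0.267 from the youngest to the oldest group. Zbtb8a (F = 6.20) and Dcun1d5 (F = 5.61) likewise were lower in males in the 3 younger groups and higher in the oldest, by 0.307 and 0.227, and adjusted p was 1.00 for each of the 3.

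Markers of nephron segments and other cell types did not pass in any comparison. Between 169 to 194 and 704 to 743 days the median differences were -0.00751 for proximal tubule (6 genes), 0.0424 for loop of Henle and distal tubule (4), -0.0109 for collecting duct (7), -0.0131 for podocyte (9), -0.00550 for endothelial cells (9) and 0.00208 for fibroblasts and matrix (31). They were 0.0245 for macrophages (10), -0.0174 for erythroid cells (9), 0.0333 for adrenal (6) and 0.112 for liver (5). Adjusted p ran from 0.678 to 0.977 over these 10 lists. Single genes of the smaller lists, Dgat2 (0.0438) and Lpl (0.00924) of adipocytes and Actn3 (0.0468) and Mylpf (-0.0527) of skeletal muscle, did not pass, and T and NK cell genes were not analysed here.

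Among the remaining lists in the same contrast, antioxidant genes (median -0.0231, adjusted p = 0.362), chaperones (-0.00931, 0.678), cytosolic ribosome (0.000725, 0.678) and imprinted and juvenile growth genes (0.0115, 0.678) did not pass. MHC and interferon genes (-0.0134, adjusted p = 0.923), complement and coagulation (0.0104, 0.923), proteasome (0.0180, 0.923), fatty acid oxidation (-0.000538, 0.923), cholesterol synthesis (-0.000906, 0.923) and the female-biased list (-0.0189, 0.923) did not pass either. Tubular injury (0.0176), senescence (0.0265), cell cycle (1.9e-05) and X-linked genes (0.00803) had adjusted p between 0.830 and 0.977. The median or mean of a list had another sign than its test in 4 or 5 of the 27 lists of each comparison, none of which passed. Across the 963 genes present in both sets, the moderated statistics correlated at 0.0658 for sex and 0.00523 between 169 to 194 and 704 to 743 days (Pearson's r across genes, which are not independent replicates). Symbols were taken from the platform table and not checked against clone sequences, so each named value holds for its clone, and for the gene only if that table is right.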

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

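The test of the rounds along the first principal component was chosen only after the result was seen; the test for single mice far from their group was fixed before. In groups of 5, the gap of the highest or lowest mouse to its nearest neighbour was compared with the group's range by Dixon's test. Chance alone gives about 1 in 20 groups past it, 9.2 of the 184 tested here, and 8 were.

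By this test, arrays of 3 mice correlated less with the other arrays of their set than those of the rest of their group. The set A array of male 17 to 44 days replicate 1 had a mean correlation of 0.891, against 0.955 to 0.959 in the other 4 mice. The set A array of female 704 to 743 days replicate 5 was at 0.944, against 0.959 to 0.964. The set B array of female 169 to 194 days replicate 5 was at 0.941, against 0.9701 to 0.9747. These were not the lowest arrays of set B. Female 704 to 743 days replicate 4 was at 0.916 and male 17 to 44 days replicate 5 at 0.922, without passing Dixon's test. Both belong to the 8 mice with outlying arrays.

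Values of 5 clones that differed between the sexes had 1 mouse far from the other 4 of its group. Selenop was at 0.107 in male 169 to 194 days replicate 2, against -0.248 to -0.147. Me1 was at -0.846 in male 704 to 743 days replicate 3, against -0.575 to -0.476. Grhpr was at -2.08 in female 17 to 44 days replicate 1, a mouse of 17 days, against -1.56 to -1.37. Unnamed spot 2601 was at -0.893 in female 169 to 194 days replicate 4, against -0.553 to -0.451. Unnamed spot 3145 was at -0.912 in male 476 to 499 days replicate 2, against -0.670 to -0.605.

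The largest pattern across arrays followed the rounds and not the groups. The rounds accounted for 64.8% of the variance along the first component in set A, the lower of the 2 sets. The component may therefore reflect array handling or mice processed at different times, and what the rounds stand for stays open. The design names no biological difference between rounds, so no biological explanation was tested.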

How the results depend on the processing

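The alternatives without mice with outlying arrays, with or without the block, the median and interquartile scaling of the lists, the tricarboxylic acid list without shared genes, and the sign flips of paired score differences were chosen only after the data were seen. Leaving single mice aside, 91 counts stayed within 1.5 times the reported value and 24 did not; 65 list results kept their direction and side of the threshold, 11 lost the call and 5 gained one; of the named clones 278 kept both, 9 lost the call, 3 gained one and 3 reversed. Unless stated, the cause was not tested. Signal over background was not used here, so its limit on dim clones is unknown. Among the dimmest 25% of their set were the named clones of Cox7b, Cox5a, Idh3b, Acy3, Ephx2, Grhpr, Kpna3 and Nudt21. So were those of Pwwp3b, Gm11545, Xist, Eif2s3y and Eif2s3x and the dimmer one of Car2.

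The round, which also pairs mice by replicate number, left a trace in the residuals, which correlated at 0.145 (set A) and 0.197 (set B) within rounds and at -0.0357 and -0.0474 between them. Not every pair within a round was over 0.1 (52.9% and 67.1% were), and not every array correlated best with its own round (23 and 27 of 40 did). As a block it called 2 clones for the age slope and 0 lists at 169 to 194 minus 17 to 44 days, where the male-biased list had an adjusted p of 0.0555; it ended or gave no other call of the results above except 1 more clone between the sexes. Exact sign flips of the 10 score differences within sex and round, 704 to 743 minus 169 to 194 days, gave p = 0.00195 for oxidative phosphorylation (the smallest they can give), 0.0137 for the tricarboxylic acid cycle and 0.0215 for the male-biased list.

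For the age slope, 2 clones were called with array weights and 1 each with adjustment within each set (fewer clones tested), a threshold of 0.1 (a looser rule), gene means, ordinary least squares, and without mice with outlying arrays, with or without the block. Gene means, and leaving out the mice of 17 to 21 days, each passed 1 list. Between 169 to 194 and 704 to 743 days, 1 clone, Car2, was called with array weights and without outlying arrays with the block. Without the mice of 17 to 21 days, 1 unnamed clone was called between the younger groups and 11 between the sexes, all among the 18.

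At 169 to 194 minus 17 to 44 days, 2 lists passed with an estimated correlation and 3 with gene means. None (0) passed, and the male-biased list lost its call, with deposited values (adjusted p = 0.0783), without the dimmest 25% (0.140), in rank form (0.351), without the mice of 17 to 21 days (0.123), with scaling (0.0704) and without outlying arrays with the block (0.0621). In rank form the male-biased list also lost its call with age (0.658) and sex (0.692), leaving 0 lists for sex. The tricarboxylic acid list lost its call with an estimated correlation (0.113) and without outlying arrays (0.0550). Oxidative phosphorylation passed in 10 of 10 alternatives at 704 to 743 minus 169 to 194 days (adjusted p from 6.03e-07 to 0.00716). Values that never passed reversed without outlying arrays: Timd2 (-0.0463 with age), Uty (-0.0388) and Ddx3x (-0.00180).

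With 1 mouse left out, calls ranged from 0 to 1 for the age slope (Igf2, without male 704 to 743 days replicate 1, female 704 to 743 days replicates 1 and 2, female 476 to 499 days replicate 2 or female 17 to 44 days replicate 4) and from 16 to 20 for sex. Lists passing ranged from 0 to 1 for the slope, 0 to 2 at 169 to 194 minus 17 to 44 days, and 1 to 3 at 704 to 743 minus 169 to 194 days (1 without male 169 to 194 days replicate 1 or 2). Adjusted p of the male-biased list ran from 0.00749 to 0.159 in the younger contrast. It was lost without male 17 to 44 days replicates 1, 3, 4 and 5, female 17 to 44 days 4 and 5, male 169 to 194 days 1 to 3, female 169 to 194 days 1 and 3, male 476 to 499 days 5, female 476 to 499 days 3 and 5, and female 704 to 743 days 1 and 4. In the older contrast the tricarboxylic acid list ran from 0.00444 to 0.0850 (lost without male 169 to 194 days replicates 1 and 2 and female 704 to 743 days 4), the male-biased list from 8.15e-04 to 0.1001 (lost without male 169 to 194 days 1 and 2 and female 169 to 194 days 1), and oxidative phosphorylation from 9.07e-07 to 5.34e-04. Uty ran from -0.0163 to 0.0330.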

Other observations

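Tests chosen only after the result was seen were the splits of mice for the 4 comparisons with 0 clones, the rounds for oxidative phosphorylation, the sex gap in old mice, the sign flips of paired differences, the complexes of oxidative phosphorylation and the youngest mice. The sex gap is the difference between males and females in the mean deviation of 17 of the 18 clones called between the sexes (1 clone per gene, so without the second Odc1 clone), each with the sign of its own sex difference. It was 0.302 at 17 to 44 days, 0.393 at 169 to 194, 0.430 at 476 to 499 and 0.282 at 704 to 743 days. Within the youngest group, the score was 0.0176 and 0.0204 in the 2 males of 17 to 21 days and 0.174 to 0.205 in the 3 older males. In females it was -0.194 to -0.172 in the 3 youngest and -0.176 to -0.170 in the other 2. These mice helped choose the clones, and with 10 assignments per sex an exact test cannot go below 0.1.

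Between 17 to 44 and 169 to 194 days, MHC and interferon genes, which serve antigen presentation and antiviral defence, had 14 of 18 higher (median 0.0609), and cytosolic ribosome genes 45 of 64 (median 0.0431). Neither passed (adjusted p = 0.0760 and 0.148); with an estimated correlation the values were 0.0472 and 0.592. MHC and interferon genes held 1 gene past the threshold adjusted over the list alone, against 0 over all clones. Endothelial markers (8 of 9 higher, median 0.0703) and imprinted and juvenile growth genes (11 of 18 lower, median -0.0196) had an adjusted p of 0.180 each.

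Of 100 splits of the mice, the real one included, 1 called as many as the 18 clones found between the sexes, and the highest other called 1. Chance is thus unlikely there, although 1 in 100 is the lowest share these splits can give. Unlike the real groups, the other splits of every comparison did not keep the rounds balanced, so they can carry differences between rounds. For the comparisons with 0 clones, 100 of 100 splits called as many for the age slope (highest other 0), 100 for 169 to 194 minus 17 to 44 days (0), 100 for 704 to 743 minus 169 to 194 days (695) and 100 for the interaction (35). Every split calls at least 0 clones, so these 4 counts could not have come out otherwise and decide nothing about chance. The split with 695 calls points to a structure of the samples: its groups accounted for 43.7% of the variance of the compared mice along the first component in the set where that share was higher, against 0.267% for the real ages taken the same way and 4.04% for the median of the other splits. At least 1 list passed in 18 of the other splits for 704 to 743 minus 169 to 194 days, and 2 of 100 splits passed as many as the 3 real ones.

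Lower oxidative phosphorylation transcripts at 704 to 743 days were weighed against chance, brightness and outlying arrays, and compared within rounds. A list p as small as the real 4.34e-07 came in 1 of 100 splits, the real one (smallest other 5.39e-05). That is the lowest share these splits can give, and at least 1 list passed in 18 of the others. The other splits did not keep the rounds balanced. Chance is thus less likely but not excluded. The median of -0.04998 lay at percentile 0 of 10000 random lists matched on brightness (central range -0.0180 to 0.0222). The random lists do not keep the correlation among the list's genes (estimated at 0.0339), so this range may be too narrow. Without outlying arrays the median was -0.0414 (adjusted p = 0.00473, alternatives from 6.03e-07 to 0.00716). The score difference was below 0 in 5 of 5 rounds. Every round held every sex and age group, so a shift shared by a whole round cancels from this contrast. That count shows only that no single round carried the difference. Scores from the youngest to the oldest group were -0.00681, 0.0256, 0.00900 and -0.0278, and the slope over all ages did not pass (adjusted p = 0.0621, past the threshold in 2 of 10 alternatives, from 0.0121 to 0.470, and in 12 of 40 fits without 1 mouse, from 0.0175 without male 17 to 44 days replicate 1 to 0.359 without male 704 to 743 days replicate 1). A biological difference with age stays open, as does a changed share of mitochondria-rich cells, since the 6 proximal tubule and 4 loop of Henle and distal tubule markers (medians -0.00751 and 0.0424) are too few to decide.

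The male-biased list was lower at 704 to 743 than at 169 to 194 days. A list p as small as the real 7.94e-04 came in 1 of 100 splits, the real one. The smallest other was close, at 8.88e-04, so that count does not exclude chance. The list score passed with exact sign flips of the differences within sex and round (8 of 10 below 0, p = 0.0215). It did not pass when sex and rounds were both ignored (permutation p = 0.0969). Odc1 alone may account for the call, since without it the list's camera p was 0.1001 (adjusted p = 0.676). A weaker male programme in old males could also lower the list: the sex gap score fell in males by 0.171 (exact p = 0.00794, the smallest that 252 assignments allow) and changed by -0.0597 in females (exact p = 0.183). That score includes Odc1 and rests on clones called in these same mice, so it cannot tell this explanation from Odc1 alone. Whether the sexes changed differently stays open, since the gap went from 0.393 to 0.282, smaller in 4 of 5 rounds, without passing (exact permutation p = 0.170).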
